A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

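The series holds 6 two-colour arrays of S. cerevisiae RNA, 4 of strain tetYFH1 and 2 of strain W303-1A, each with RNA from cells treated with doxycycline in one channel and from untreated cells in the other. Per the labels' protocols, cells were harvested from 30 ml of YPG culture at 30 °C and an A600 of 0.5, and 8 µg of total RNA was labelled indirectly with Cy5 or Cy3. In Exp 1 of each pair the treated sample carried Cy5, and in Exp 2 it carried Cy3. The authors deposited 1 log2 ratio per ORF and array, for 6174 ORFs with no missing value. Scanning, background correction, normalization between dyes, averaging of spots and filters are not given in the sources used here, nor is the type of probe. The labels describe each ratio as treated over untreated, and YFH1 below 0 on all 4 tetYFH1 arrays bears this out there, while the direction of the W303 arrays rests on the labels alone. The base of the logarithm was read from the values: on B1 and B2, 2 raised to the value was a number of 3 decimals for 100% of the ORFs (tolerance 1e-04 in the last decimal).

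The deposited values were used without further normalization. Array medians were 0.03 (A1), 0.02 (A2), 0.00 (B1), 0.21 (B2), 0.07 (W303 array 1) and 0.02 (W303 array 2). Exactly whole log2 numbers made up 2603 values (42.2%) of B1 and 1524 (24.7%) of B2, and at most 8 values of any other array. The labels do not mention this, and the values were kept. ORF names were matched to the locus tags of the R64 assembly's gene table, which was used for names alone: 5675 matched, 499 did not and kept their ORF name, and 5158 had a symbol other than their locus tag. No coordinates were used.

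The 2 arrays of a dye-swap pair were averaged, so that a dye effect cancels, and each pair counted as 1 replicate. A linear model with 1 coefficient per strain was fitted to the 3 pair means with limma 3.58.1 in R 4.3.3, and tested with empirical Bayes moderation (1 residual and 6.64 prior degrees of freedom). The tetYFH1 mean, the W303 mean and the difference between them were tested against 0, two-sided, with Benjamini-Hochberg adjustment over the 6174 ORFs and a threshold of 0.05 on the adjusted p. Since W303 had 1 pair, the spread came from tetYFH1. For 41 gene lists, which cover iron, mitochondria, carbon metabolism, stress, amino acids, metals, ribosomes, the cell cycle and cell identity, members past the threshold were counted over all genes and adjusted over the list alone. The 40 lists with at least 4 measured genes were tested with camera (preset correlation 0.01, two-sided) for tetYFH1 and for the difference, with adjustment over the lists. The remaining list, the genes of the mitochondrial genome, had 0 measured genes. The lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined.

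Genes were named by rule. YFH1 came first. For tetYFH1 and for the difference, the 10 genes with a symbol and the largest means in each direction were named among those past the threshold with the same sign on all 4 tetYFH1 arrays, filled where fewer passed with genes of at least 2-fold change and the same sign on 4 arrays. For W303, the 5 largest in each direction with the same sign on both arrays and at least 2-fold change were named. Of each list that passed, up to 4 genes with the smallest p in the list's direction were eligible. The other genes among the 25 that passed were named after their values had been seen.

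The alternatives were each array as a replicate, with and without the Exp number as a term, arrays of one letter as a random block, averages over arrays of one Exp number, centring and scaling of the arrays, robust moderation, a 2-fold minimum, an adjusted p under 0.1, camera with an estimated correlation or on ranks, and omission of each array and each pair. Without a pair, the pair means leave no residual degree of freedom, so the arrays left were entered singly as replicates. For lists, correlations were also estimated on the arrays as replicates, and ORFs with whole numbers on B1 or B2 were left out as a further alternative. The W303 ratios were also turned to untreated over treated, for the counts, the lists, the named genes and the relation across genes.

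The gene test was tested on simulated data of the same size, in 20 runs. Each run had 200 changed genes, split evenly over changes of 1, 2, 3 and 4 in log2 ratio. With gene spreads drawn from the fitted prior, 48.9% of changes of 1 in log2 ratio were recovered in tetYFH1, 99.4% of changes of 2 and 100% of changes of 3 or 4. For the difference between strains these shares were 4.9%, 62.1%, 97.9% and 99.8%. Of the calls, 11.8% were false (3.05% to 23.1% per run) against a nominal 5%. With 1 residual degree of freedom the prior degrees of freedom were poorly estimated (median 9.84 where 6.64 was simulated). Whether this caused the excess of false calls was not tested. With the moderated spreads as the simulated ones, recovery in tetYFH1 was 80.2% at 1 and 99.9% at 2, and 8.19% of calls were false. The first spread model was chosen after the second had been seen. A list of rising genes passed in 20 of 20 runs and a list of unchanged genes in 0. The simulated pairs had equal spread and no shift of a whole array. In the data the SD was 0.744 on B1 and 0.397 on A1, and the median of B2 was 0.21. The simulated shares of recovered and false calls may therefore not hold for these data. The simulated genes were also drawn independently of each other. In the data the estimated correlation differed between lists, with −0.029 for glycolysis, 0.720 for cytosolic ribosomal proteins and 0.778 for reserve carbohydrates. The runs therefore do not measure how often a list of correlated genes is called falsely. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.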

Results

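Transcript levels of 6174 open reading frames (ORFs) of Saccharomyces cerevisiae were measured on 6 two-colour arrays, to follow what happens to gene expression when yeast frataxin is switched off. Frataxin, the product of YFH1, is a mitochondrial protein that serves the assembly of iron-sulfur clusters. In the strain tetYFH1 the gene stands under a tet promoter that doxycycline turns off, and W303-1A (here W303) is the unmodified background strain and the control for the antibiotic. The cells grew on YPG, a rich medium with glycerol, a carbon source that yeast can use only by respiration. Each array compared cells after 10 h with 2 µg/ml doxycycline with untreated cells of the same strain. The titles read 0 h against 10 h, so the untreated cells are taken as those of 0 h. The drug and the 10 h therefore cannot be told apart within a strain. Every value is the deposited log2 ratio of treated over untreated. The tetYFH1 strain had 4 arrays in 2 dye-swap pairs, pair A (arrays A1 and A2) and pair B (arrays B1 and B2), and W303 had 2 arrays in 1 pair. Each pair was averaged and counted as 1 replicate, so n = 2 for tetYFH1 and n = 1 for W303, whose single pair was assumed to vary like those of tetYFH1. The labels do not say whether pairs or arrays come from separate cultures, so the p-values measure only the spread between these samples, which can be technical, and the number of arrays limits the precision. The SD of the log2 ratios was 0.744 on B1 and 0.654 on B2, and between 0.392 (A2) and 0.459 (W303 array 2) on the other arrays.

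YFH1 itself was examined first, as a check of the labels. YFH1 (YDL120W) fell after doxycycline in tetYFH1 and stayed near its untreated level in W303. Its log2 ratio was −2.64 on A1, −3.29 on A2, −5.38 on B1 and −5.11 on B2, against −0.08 and −0.05 on the W303 arrays. The mean in tetYFH1 was −4.11 ± 1.61 (SD, n = 2), or 17.2-fold lower, with a limma adjusted p of 0.0177. Over the alternatives tried, the YFH1 log2 ratio in tetYFH1 lay between −5.24 and −2.97, and its adjusted p reached 0.836 (without B2). The adjusted p also missed the threshold without A2 (0.401), without B1 (0.171), after centring (0.15), after scaling (0.0552), without ORFs with whole numbers on B1 or B2 (0.0511) and with robust moderation (0.316). Where a whole pair is left out, here and for the counts and lists, the arrays left were entered singly as replicates, since pair means then leave no residual degree of freedom. Such results differ in 2 choices from the others; YFH1 had an adjusted p of 6.52e-04 without pair A and 4.44e-12 without pair B, against 9.94e-04 with all arrays entered singly. The difference between the strains was −4.04 (SE 0.807, 95% interval −5.92 to −2.17) and did not pass after adjustment over all genes (adjusted p 0.571). The neighbours of YFH1 on its chromosome, HEM25 (YDL119C, a mitochondrial glycine carrier for heme synthesis) and EXP1 (YDL121C), had log2 ratios of −0.19 and −0.09 in tetYFH1 and did not pass.

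The first comparison asked which genes change after 10 h of doxycycline where it turns off YFH1. The genes that fell in tetYFH1 were mostly those with which yeast lives on non-fermentable carbon and those of the general stress response. To the first group belonged ACS1, which makes acetyl-CoA from acetate, the mitochondrial citrate synthase CIT3, the acetate and ammonium transporters ADY2 and ATO3, POX1, the first enzyme of peroxisomal fatty acid oxidation, the mitochondrial aldehyde dehydrogenase ALD4, ICL2 and GIP2, all in the list of targets of the activator Adr1. The stress genes included the desiccation proteins GRE1 and SIP18, the cytosolic catalase CTT1, the aldehyde dehydrogenases ALD2 and ALD3, GND2, MSC1 and the protease inhibitor PAI3. With them fell the formate dehydrogenase FDH1, the serine and threonine deaminase CHA1, and TKL2 and NQM1, the minor transketolase and transaldolase. No gene rose past the threshold.

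Of the 6174 ORFs, 25 passed an adjusted p of 0.05 in tetYFH1 with limma, 0 higher and 25 lower, while 584 (9.46%) had an unadjusted p under 0.05. All 25 were lower on 4 of 4 tetYFH1 arrays, and the smallest fall among them was −1.55 (MMS21, a SUMO ligase). GRE1 (YPL223C) had a mean log2 ratio of −4.02 ± 0.99 (SD, n = 2, adjusted p 0.00944). It read −4.72 on both A1 and A2, the lowest value of each array, so the size of its fall in pair A is uncertain. FDH1 (YOR388C) had −3.05 ± 0.33, ACS1 (YAL054C) −2.69 ± 0.45 and CIT3 (YPR001W) −2.48 ± 0.18 (SD, n = 2), each with an adjusted p of 0.00944. SIP18 (YMR175W) followed with −2.68 ± 0.91, NQM1 (YGR043C) with −2.47 ± 0.77, HBT1 (YDL223C) with −2.41 ± 0.94, ALD3 (YMR169C) with −2.39 ± 0.80 and TKL2 (YBR117C) with −2.31 ± 0.44 (SD, n = 2), at adjusted p values between 0.0155 and 0.0284. The remaining 15 genes apart from YFH1 lay between −2.25 and −1.55. Of the 25, 16 were in the Adr1 or general stress lists, which share 0 genes. ALD2 and ALD3 are near-identical neighbours and the ORF YBR116C overlaps TKL2, so each of these signals is uncertain as to its gene. On B1 or B2, 15 of the 25 had an exactly whole log2 number, and without such ORFs 3 of the other 10 passed. The count was not stable: it was 15 without A1, 0 without A2, B1 or B2, 25 without either W303 array and 0 after centring each array on its median. With each array as a replicate it was 86. With 1 tetYFH1 pair left out and the other arrays, those of W303 included, entered singly, it was 106 (without pair A) or 300 (without pair B). The 25 genes kept their sign in every one of these settings. This follows from their being well below 0 on all 4 tetYFH1 arrays and is no further support.

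**Figure D1:**
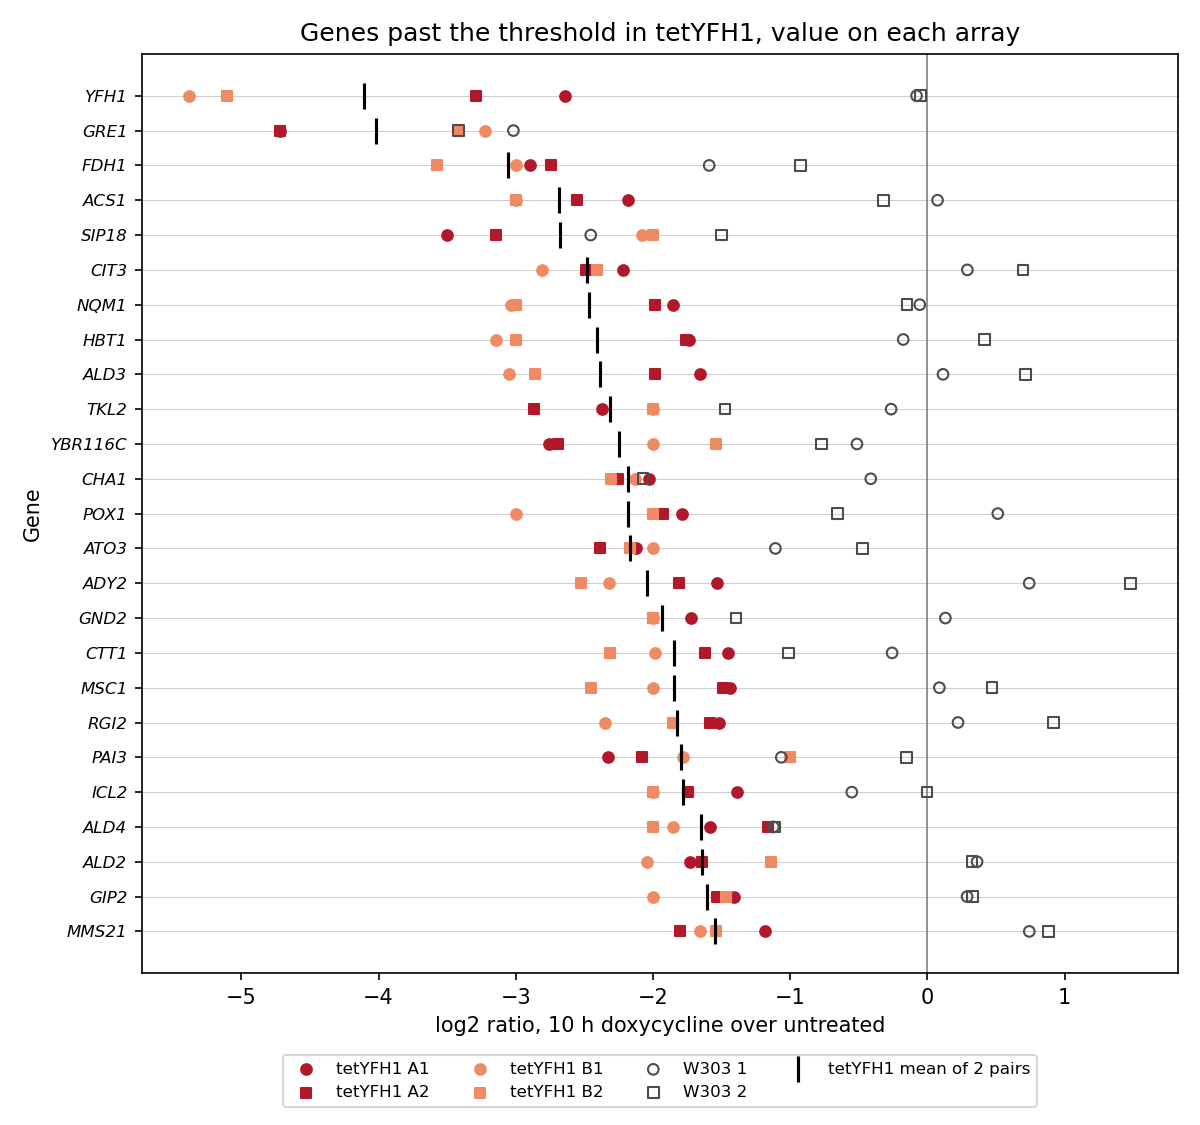
Log2 ratio of doxycycline over untreated (x axis) on each array for the 25 genes (y axis) that passed in tetYFH1; filled points are tetYFH1 arrays, open points W303 arrays, and black bars the mean of the 2 tetYFH1 pairs. All tetYFH1 points lie below 0. GRE1, SIP18, FDH1, CHA1 and ALD4 also lie at least 2-fold below untreated in the W303 mean, if the W303 ratios run as labelled.

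The largest rises in tetYFH1 were in NCE101, the exocyst subunit SEC5, the GTPase TEM1, UPS2 and UTR2, and in none of them did the rise pass. There were 24 genes with at least 2-fold higher means and the same sign on all 4 arrays. NCE101 (1.98) and TEM1 (1.74) owed their means largely to array B1, where they read 6.94 and 5, and BET1 (1.37) read 4 there. SEC5 (1.79) also had its largest value, 4.33, on B1, but read 1.57 on A1 and 0.77 on A2. ARB1 (1.34) had its largest value, 3.28, on A2. UPS2 (1.69), UTR2 (1.57), SAM1 (1.42), MUP1 (1.29) and PRP43 (1.25) completed the 10 largest. The adjusted p of these 10 genes lay between 0.0863 and 0.501.

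Gene lists fixed beforehand were then tested as sets, to ask which processes shifted in tetYFH1 more than other genes. As sets, the Adr1 targets, the general stress genes and the genes of the glyoxylate cycle and gluconeogenesis shifted down in both pairs. Reserve carbohydrate genes, which make and break down glycogen and trehalose, had a median below 0 in pair B and above 0 in pair A, and the list was called down over both pairs. Cytosolic ribosomal protein genes shifted up, and more so in pair B than in pair A. Smaller shifts were found for glycolysis, the proteasome and genes of quiescent and sporulating cells (down) and for mitochondrial ribosomal proteins, lysine synthesis and the cell cycle (up). None of these calls held with a correlation between genes estimated on the arrays, where the adjusted p of the lists lay between 0.129 and 0.668. On pair means the calls were also lost where the estimated correlation lay below the preset 0.01, as for glycolysis (−0.029) and mitochondrial ribosomal proteins (−0.013). The test with an estimated correlation has few degrees of freedom here, so its losses cannot separate correlation between genes from the small number of arrays. Glycolysis (W303 median −0.35, 18 of 21 below 0) and mitochondrial ribosomal proteins (W303 median 0.40, 65 of 67 above 0) had W303 medians on the same side of 0 as in tetYFH1, if the W303 ratios run as labelled; no set test was run in W303 alone.

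The 26 Adr1 targets had a median log2 ratio of −1.17 in tetYFH1 (pair A −0.99, pair B −1.70), with 24 of 26 below 0, and 8 of them passed over all genes and 20 when adjusted over the list alone. Their set test gave an adjusted p of 1.47e-33, against 0.129 with an estimated correlation between genes. The 30 general stress genes had a median of −1.02 (pair A −0.53, pair B −1.45), with 8 genes lower over all genes and 18 adjusted over the list alone (adjusted p 1.47e-29, against 0.201 with an estimated correlation). All 15 glyoxylate and gluconeogenesis genes lay below 0, with a median of −0.51, and 1 (ACS1) passed over all genes and 4 adjusted over the list alone (adjusted p 6.95e-11, against 0.201 with an estimated correlation). Among them MDH2 (−1.20), YAT2 (−1.11) and the lactate transporter JEN1 (−1.26) were the next after ACS1 and did not pass over all genes. The 18 reserve carbohydrate genes had a median of −0.48 but 0.14 in pair A and −0.97 in pair B, and 0 passed with limma over all genes or adjusted over the list alone (set test adjusted p 2.80e-04, against 0.668 with an estimated correlation). Without ORFs with whole numbers on B1 or B2 the median was −0.133 and the call was lost (adjusted p 0.0836). The call was also lost without pair B, where the set test pointed up (median 0.145, adjusted p 0.400). Glycogenin GLG1 (−1.0) and the phosphatase subunit GAC1 (−1.09) had their lowest values in pair B. The 21 glycolysis genes (median −0.16) and the 34 proteasome genes (median −0.14) had 0 members past the threshold over all genes or adjusted over the list alone, with set test adjusted p values of 0.00112 and 2.36e-04, against 0.668 and 0.652 with an estimated correlation. The glycolysis call was lost without B2 (adjusted p 0.525) and the proteasome call without pair B (0.156) and without ORFs with whole numbers (0.0731). The 20 genes of quiescent and sporulating cells, among them FMP45 (−2.36) and the meiotic inducer IME1 (−1.19), had a median of −0.18, 0 genes past the threshold over all genes and 4 adjusted over the list alone (adjusted p 0.00112, against 0.335 with an estimated correlation). For the 30 oxidative stress genes the median (0.04) and the mean (−0.13) differed in sign, and the set test pointed down (adjusted p 0.0377, against 0.668 with an estimated correlation), with CTT1 the 1 gene that passed over all genes and 2 lower adjusted over the list alone. That call was also lost without A2 (0.0683), without B2 (0.525), without either pair, without ORFs with whole numbers (0.188) and after centring (0.0518). The list of YFH1 with HEM25, EXP1 and CDC13 (4 genes, the last not a neighbour of YFH1) had a median of −0.14 and a mean of −1.08, and passed (adjusted p 0.0163, against 0.461 with an estimated correlation) through YFH1, its 1 gene past the threshold over all genes and adjusted over the list alone, and lost the call without A2 (0.0669) or B2 (0.213).

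Of the lists that shifted up, the cytosolic ribosomal proteins were the largest, with 131 of 133 genes above 0 and a median log2 ratio of 0.63 (pair A 0.21, pair B 1.00). Their set test gave an adjusted p of 1.64e-23, against 0.652 with an estimated correlation, and 0 genes passed with limma over all genes or adjusted over the list alone. RPL7A (0.91), RPS22A (1.16), RPL21B (0.91) and RPL5 (0.70) had the smallest p values, and copies of ribosomal protein genes share much of their sequence. The 67 mitochondrial ribosomal proteins had a median of 0.24 (pair A 0.23, pair B 0.23; adjusted p 0.00188, against 0.668 with an estimated correlation), led by RSM26 (0.71) and MRPL39 (0.71), and lost the call without pair A (0.173). The 27 cell cycle genes, among them DSE2 (0.59) and the ribonucleotide reductase RNR1 (0.87), had a median of 0.32 (adjusted p 0.00426, against 0.461 with an estimated correlation), and missed the threshold without pair B (0.0564). The 10 lysine synthesis genes, among them the homoaconitase LYS4 (0.68), had a median of 0.36 (adjusted p 0.0346, against 0.652 with an estimated correlation). The lysine call was lost without A1 (0.0611), without B1 (0.0984) and without pair B (0.409). In these 3 lists too 0 genes passed over all genes or adjusted over the list alone. With correlations estimated on the pair means, which leave 1 residual degree of freedom, every list had an adjusted p of 0.908 or higher. The deposited values are not centred, and the median of all genes was 0.108 in tetYFH1. After centring, the medians of the lists that had passed kept their sign except that of oxidative stress, which became −0.03, and the cytosolic ribosomal proteins then had a median of 0.56.

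**Figure D2:**
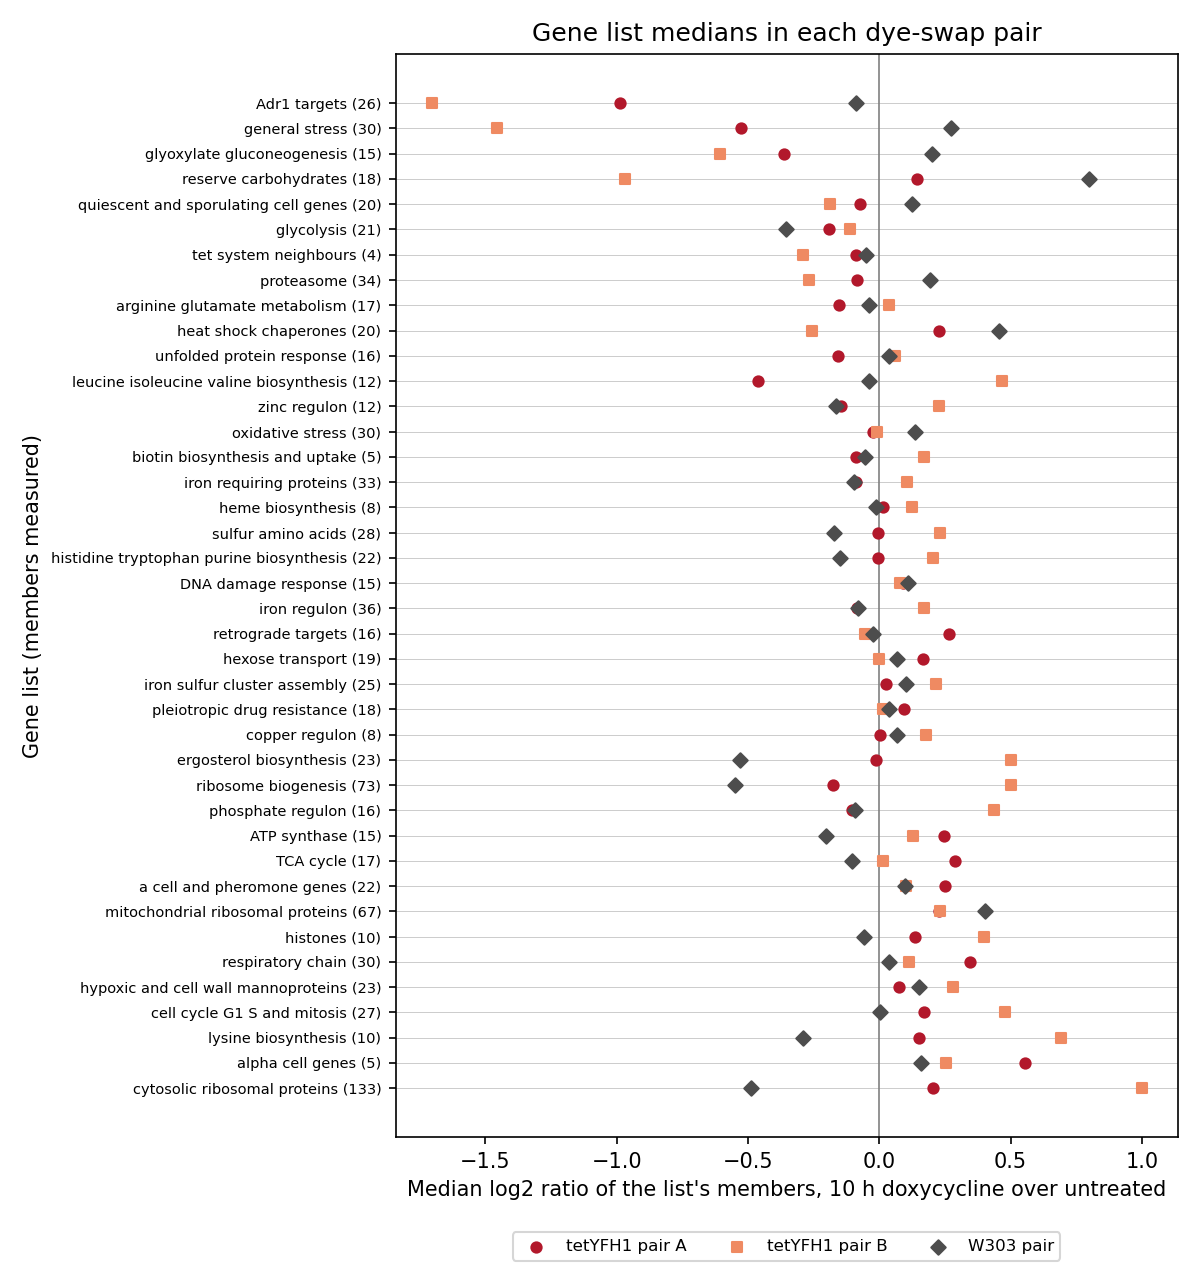
Median log2 ratio of doxycycline over untreated (x axis) for each of the 40 measured gene lists (y axis, number of measured genes in brackets) in tetYFH1 pair A (circles), tetYFH1 pair B (squares) and the W303 pair (diamonds). Adr1 targets lie at −0.99 and −1.70 in the tetYFH1 pairs and at −0.09 in W303, and cytosolic ribosomal proteins at 0.21, 1.00 and −0.49.

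Loss of frataxin is known for its effects on iron, so the lists of iron genes were looked at in the same way. The iron regulon, the uptake genes that the activator Aft1 turns on, did not shift as a set in tetYFH1, and neither did the genes of iron-sulfur cluster assembly, heme synthesis, the respiratory chain or the ATP synthase. The 36 iron regulon genes had a median log2 ratio of 0.10 (pair A −0.09, pair B 0.17), 0 genes passed with limma over all genes or adjusted over the list alone, and the set test gave an adjusted p of 0.582. The medians were 0.12 for the 25 iron-sulfur assembly genes (adjusted p 0.738), 0.07 for 8 heme synthesis genes (0.738), 0.26 for 30 respiratory chain genes (0.185) and 0.21 for 15 ATP synthase genes (0.305). Of the 33 iron-requiring proteins, the catalase CTT1 was the 1 gene that passed over all genes, against 1 higher and 2 lower adjusted over the list alone (median 0.07, adjusted p 0.350). CIT3 was the 1 gene of the 17 of the TCA cycle that passed (median 0.21, adjusted p 0.695), and ATO3 the 1 of 16 targets of the retrograde pathway (median 0.10, adjusted p 0.308). The 73 ribosome biogenesis genes had a median of 0.20 (pair A −0.18, pair B 0.50, adjusted p 0.350). Heat shock chaperones (−0.004, adjusted p 0.350) and ergosterol synthesis (0.18, adjusted p 0.191) did not shift either. In all, 13 of the 40 lists tested passed in tetYFH1 with the preset correlation, 9 down and 4 up, and 0 of the 13 with an estimated one; the medians of the others lay between −0.01 (arginine and glutamate metabolism) and 0.37 (genes of alpha cells).

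The W303 arrays asked what changes after 10 h of doxycycline where YFH1 is not under the tet promoter. In W303 the largest falls were again in GRE1 and SIP18, followed by the glycerol transporter STL1, MRH1 and PWP1. The largest rises were in RGI1, AIM17, the amino acid permease GAP1, the peroxisomal citrate synthase CIT2 and the small heat shock protein HSP42. None of these passed, and their direction rests on the labels alone. With limma 0 of 6174 genes passed in W303 (smallest adjusted p 0.999), and 162 (2.62%) had an unadjusted p under 0.05. That share is below the nominal 5%, so the spread taken from tetYFH1 may be too wide for W303. The absence of calls in W303 therefore does not show that no gene changed. With each array as a replicate, GAP1 and GRE1 passed, 2 genes in all. Without W303 array 1 the count was 3, and with arrays entered singly it was 1 without pair A and 281 without pair B. The means on 2 of 2 arrays were −3.22 for GRE1, −1.98 for SIP18, −1.61 for STL1, −1.57 for MRH1 and −1.54 for PWP1, and 2.37 for RGI1, 1.89 for AIM17, 1.88 for GAP1, 1.78 for CIT2 and 1.70 for HSP42. There were 27 genes with at least 2-fold higher and 61 with at least 2-fold lower means and the same sign on both arrays.

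The 25 genes that passed in tetYFH1 were compared with the same genes in W303. They had been selected by their change in tetYFH1, which itself sets them apart from W303. Their median log2 ratio was −2.18 in tetYFH1 and −0.12 in W303, and 25 of 25 were lower in tetYFH1, but the difference passed in 0 of them (adjusted p 0.387 or higher). Genes were therefore also picked on pair A alone: 46 were at least 2-fold lower on both A1 and A2, the 25 among them. Their median log2 ratio was −2 in pair B and −0.07 in W303, and 43 of 46 were lower in pair B than in W303. In the other direction, 188 genes were at least 2-fold lower on both B1 and B2, with a median of −0.33 in pair A and 0.16 in W303, and 149 of them were lower in pair A. These shares depend on the direction of the W303 ratios, which rests on the labels alone, and with them turned they would be 44 of 46 and 119 of 188. The 29 genes at least 2-fold lower on both W303 arrays had medians of −0.22 in pair A and 0.80 in pair B. Of the 25 genes in W303, 13 lay below 0 on both arrays and 8 above 0 on both. GRE1, SIP18, FDH1 (−1.26), CHA1 (−1.24) and ALD4 (−1.12) were at least 2-fold lower in W303 as well, while ADY2 (1.11) and MMS21 (0.81) were higher there. With the W303 ratios turned, these signs would be the opposite, so that GRE1 would have 3.22 and SIP18 1.98 in W303 and only ADY2 would be at least 2-fold lower there; 25 of 25 genes would still be lower in tetYFH1. Across all genes, which are not independent replicates, the responses of the strains were nearly unrelated (Pearson's r −0.0892, Spearman's rho −0.0834). By pair, r with W303 was 0.217 for pair A and −0.248 for pair B, and the tetYFH1 pairs had an r of 0.309 with each other. Among the 25 genes r between the strains was 0.486. With the W303 ratios turned, each r with W303 would keep its size and change its sign.

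The difference between the strains was then tested itself, as the measure of what changed in tetYFH1 beyond the change in W303. Among genes with the same sign on all 4 tetYFH1 arrays, those with the lowest tetYFH1 response relative to W303 were YFH1, FMP45, ADY2, CIT3, ALD3 and CIT2, followed by ACS1, HBT1, the amino acid permease DIP5 and RGI2. The highest, under the same limit, were MRH1, the sterol desaturase ERG5, the methionine permease MUP1, UTR2, SAM1, ARB1, YHM2, UPS2, IMD4 and RPS22A. None of them passed, and the order depends on the direction of the W303 ratios, which rests on the labels alone. With these turned, CIT2 (0.86) would lie higher, and MRH1 (−0.60) and ERG5 (−0.28) lower, in tetYFH1, while YFH1 would have −4.17, ACS1 −2.81, CIT3 −1.99, ALD3 −1.97, FMP45 −1.48 and ADY2 −0.94. Lists depend on that direction too. With the W303 ratios turned, the median difference would be 0.48 for reserve carbohydrates, −0.38 for ribosome biogenesis and −0.31 for ergosterol synthesis. With the ratios as labelled, Adr1 targets, general stress genes, reserve carbohydrates and the glyoxylate cycle lay lower as sets in tetYFH1 than in W303. Cytosolic ribosomal proteins, ribosome biogenesis and ergosterol synthesis lay higher. None of these list calls held with an estimated correlation (adjusted p 0.249 to 0.664 on the arrays, 0.878 on pair means).

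For the difference, 0 of 6174 genes passed with limma (smallest adjusted p 0.387), and 391 (6.33%) had an unadjusted p under 0.05. With each array as a replicate 8 passed, all lower in tetYFH1, namely ACS1, ADY2, MMS21, GIP2, RGI2, GAP1, ALD3 and CIT3, of which all but GAP1 are among the 25, and on the arrays left without pair A or pair B 100 or 140 passed. The differences in log2 ratio were −3.24 for FMP45, −3.16 for ADY2, −2.97 for CIT3, −2.80 for ALD3, −2.71 for CIT2 and −2.56 for ACS1, and 2.54 for MRH1, 2.37 for ERG5 and 2.12 for MUP1. Of the 40 lists, 17 passed, 7 higher and 10 lower in tetYFH1. This tally depends on the direction of the W303 ratios: if they were turned, 9 would pass, and the median difference would be 0.48 for reserve carbohydrates, −0.38 for ribosome biogenesis and 0.18 for cytosolic ribosomal proteins. With a correlation estimated on the arrays 0 passed, at adjusted p values from 0.249 to 0.664. The median difference was −1.21 for general stress genes (11 lower adjusted over the list alone, set test adjusted p 8.01e-23), −0.81 for Adr1 targets (9 lower, 6.04e-16) and −1.13 for reserve carbohydrates. It was 1.12 for cytosolic ribosomal proteins, 0.73 for ribosome biogenesis and 0.62 for ergosterol synthesis, with 0 genes past the threshold adjusted over each list alone. Apart from the Adr1 targets, these lists had medians of opposite sign in pair B and W303: cytosolic ribosomal proteins had 1.00 in pair B and −0.49 in W303, general stress genes −1.45 and 0.27, and reserve carbohydrates −0.97 and 0.80. On single arrays, the ribosomal median minus the stress median was 0.670 and 0.813 on A1 and A2, 2.47 on both B1 and B2, and −0.865 and −0.702 on the W303 arrays. With the W303 ratios turned, these lists would have medians of the same sign in pair B and W303. The single-array values of W303 would then be above 0.

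**Figure D3:**
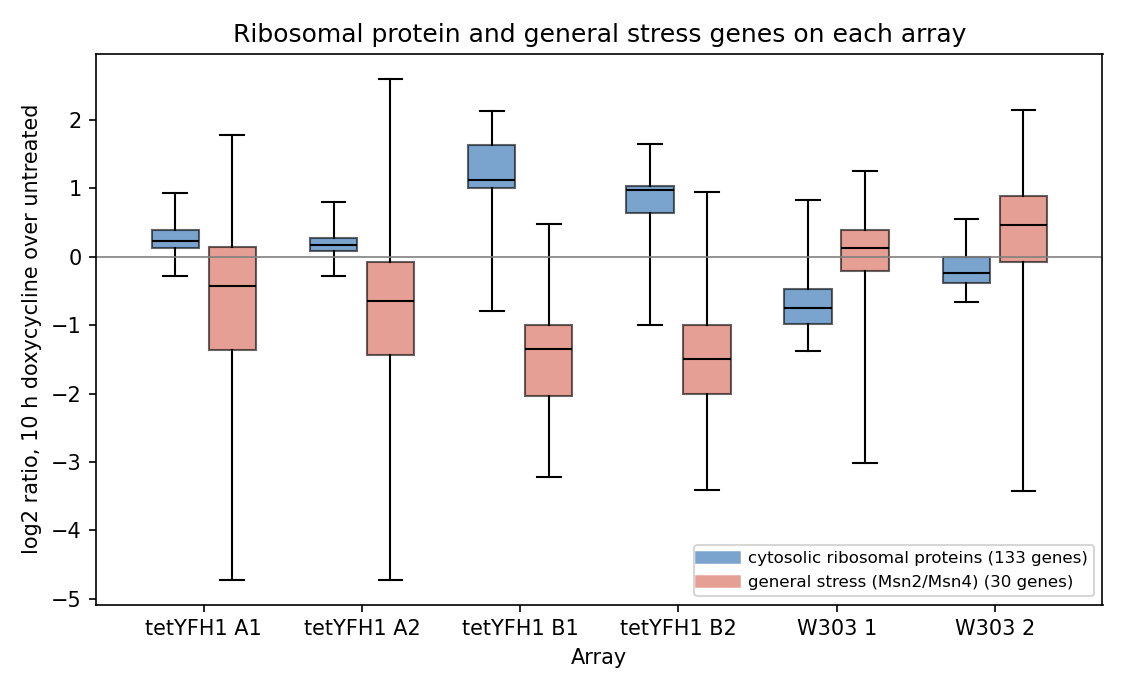
Log2 ratios of doxycycline over untreated (y axis) of the cytosolic ribosomal protein genes and the general stress genes on each array (x axis); boxes span the quartiles, whiskers the lowest to highest gene, and black lines the medians. The ribosomal median lies above the stress median on the 4 tetYFH1 arrays, by 2.47 on B1 and B2. It lies below the stress median on the W303 arrays, if their ratios run as labelled.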

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

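The tests on the genes that fell in tetYFH1, and those of decimals dropped from values and of missing values set to 0, were chosen after the result was seen; the others were not.

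Among the named genes, 10 of 118 had an array far from the other 3 of tetYFH1, and 6 of these arrays were B1. Chance alone marks about 5% of genes where the values are independent and of equal spread. The arrays are paired and B1 had the widest spread (SD 0.744), so these counts are not measured against chance. On B1, NCE101 read 6.94 (others 0.01 to 0.70), TEM1 5 (others 0.30 to 0.87), CLB1 1.27 (others 0.22 to 0.36), TIM11 1 (others 0.23 to 0.33), TPS3 −0.52 (others 0.18 to 0.26) and PRE2 −1 (others −0.14 to −0.12). On B2, PWP1 read 0.84 (others −0.30 to −0.11) and PCL1 1.405 (others −0.03 to 0.12). GND2 read −1.725 on A1, where the other arrays read −2, and SPG4 −0.64 on A2 (others −1 to −0.96).

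For 17 lists the response to doxycycline differed between tetYFH1 and W303 by the set test on the difference with a preset correlation, and for 0 of them with an estimated one. The median difference, tetYFH1 minus W303, was negative for general stress genes (−1.21), reserve carbohydrates (−1.13), Adr1 targets (−0.81), glyoxylate and gluconeogenesis (−0.74), the proteasome (−0.35), heat shock chaperones (−0.30), the list of YFH1 with nearby genes (−0.24), oxidative stress (−0.20), quiescent and sporulating cells (−0.20) and mitochondrial ribosomal proteins (−0.17). It was positive for cytosolic ribosomal proteins (1.12), lysine synthesis (0.73), ribosome biogenesis (0.73), ergosterol synthesis (0.62), the ATP synthase (0.46), the cell cycle (0.36) and sulfur amino acids (0.28). The calls and signs depend on the direction of the W303 ratios, which rests on the labels alone. With these turned, the set test would reverse for 8 of the 17 lists, among them mitochondrial ribosomal proteins (median 0.66) and ribosome biogenesis (−0.38). Cytosolic ribosomal proteins would have 0.18. Without W303 array 1 the calls of the ATP synthase (median 0.152, adjusted p 0.843) and of the YFH1 list (−0.413, 0.0735) were lost. Without W303 array 2, 6 of the 17 were lost: heat shock chaperones (−0.0403, adjusted p 0.291), oxidative stress (−0.0131, 0.291), sulfur amino acids (0.0129, 0.617), mitochondrial ribosomal proteins (−0.0140, 0.83), the cell cycle (0.304, 0.171) and the YFH1 list (−0.0691, 0.155).

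The fall of 25 genes in tetYFH1 was weighed first, since doxycycline or the 10 h themselves, rather than the loss of YFH1, would lower the same genes in W303. Since the 25 genes were selected by their fall in tetYFH1, the test took the 46 genes at least 2-fold lower on A1 and A2, whose median difference, pair B minus W303, was −1.37 with an upper quartile of −0.45, short of the bound of −0.5, which it would meet only with the W303 ratios turned (upper quartile −1.18), so the drug and the time stay open. The difference between the strains passed in none of the 25 on pair means, in 7 of them with each array as a replicate, and in GRE1, FDH1 and CHA1 with the W303 ratios turned, and for the 5 genes at least 2-fold lower in W303 too (GRE1, SIP18, FDH1, CHA1 and ALD4) its median was −0.80, which leaves the same question open. Whole-number values of pair B are argued against as the source, since the Adr1 targets fell to a median of −0.99 in pair A, which has almost none, with 25 of 26 (96.2%) below that pair's median. A response to the loss of frataxin remains as a hypothesis beside the drug and the time, and differences between the cultures of each strain at harvest were not tested.

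Ribosomal protein and general stress genes moved apart, strongly in pair B, weakly in pair A and the opposite way in W303. Among 60 ribosomal protein genes without whole values, pair B lay 0.88 above pair A (1.11 against 0.23), which argues against the whole numbers as the source. The dye is argued against too, since the difference of ribosomal and stress medians varied by at most 0.164 within a pair and by at least 1.37 between pairs, a gap of 1.21. If the cultures' growth or stress state were the cause, growth and stress genes would account for the negative correlation of pair B with W303. The correlation was −0.205 over the 5903 genes outside those lists, against −0.248 over all genes and −0.427 in the 271 left out. That is just past the bound of −0.2 set in advance, below which it would count against this cause. Its 95% interval, which the bound as set did not include, reached above −0.2, so this stays open. The strain, which the design varies, and the direction of the W303 ratios, which rests on the labels alone, remain open as untested, and neither separates pair A from pair B.

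The whole numbers on B1 and B2 were the last pattern weighed, and no biological explanation of them was tested. Rounding to the nearest whole number is in line with the data: ORFs at exactly 1 on B1 had a mean on B2 only 0.0367 higher (95% interval −0.0279 to 0.101) than ORFs at 0.5 to 1.5, and for exactly −1 against −1.5 to −0.5 the difference was −0.069 (95% interval −0.160 to 0.0218). Dropped decimals are argued against, since 34.4% of the whole values were not 0, against 12.4% of the other values lying at least 1 from 0, a gap of 22.0 percentage points (95% half-width 2.12). This comparison replaced one set in advance, ORFs at exactly 1 against those at 1 to 2 (−0.130, 95% interval −0.216 to −0.0446), which had left the matter undecided. Missing values filled with 0 are argued against as the source of all whole numbers by the same share, 34.38% of whole values being other numbers. Whether some of the 1708 zeros on B1 and 880 on B2 are such fills cannot be told from this share. On both arrays 904 ORFs were whole, against 643 by chance.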

How the results depend on the processing

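Leaving out ORFs with whole numbers on B1 or B2, turning the W303 ratios, estimating the correlation with each array as a replicate, and running lists with each array as a replicate, averaged by Exp number, scaled or with arrays or pairs left out were chosen after seeing the data; the others were planned.

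The number of genes that passed in tetYFH1, 25, rose to 86 with each array as a replicate, 99 with arrays of one letter as a random block, 132 with arrays of one Exp number averaged and 39 at an adjusted p under 0.1. The random block used a correlation of −0.0725 between arrays of one letter. It therefore made no allowance for likeness within a pair and treated the arrays nearly as independent. It fell to 0 after median centring, to 0 after centring and scaling, and to 3 without ORFs with whole numbers. Leaving out 1 array gave 0 to 25 genes. Without a pair the arrays left were entered singly, since pair means then leave no residual degree of freedom, so 2 choices changed at once; this gave 106 and 300 genes, against 86 with all arrays entered singly. For the difference, 0 became 8 (arrays), 10 (random block) and 29 (Exp averaged), 0 with 1 array left out, and 100 and 140 without a pair (arrays entered singly). For W303, 0 became 2, 3 and 1 in these settings, 0 to 3 with 1 array left out, and 1 and 281 without a pair (arrays entered singly). With the Exp number as a block, 59 genes passed in tetYFH1, 4 in the difference and 0 in W303. Exp 1 minus Exp 2 had r −0.175 between the strains across genes and 0.111 between the tetYFH1 pairs. Robust moderation gave 22 genes in tetYFH1, all among the 25.

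The 25 genes kept their sign in every setting in which they were entered. Being well below 0 on every tetYFH1 array, they could not have changed it, so this is no further support. After centring their median moved from −2.18 to −2.24, so the folds did not shrink in the median. The prior degrees of freedom fell from 6.64 to 4.28, the prior variance fell from 0.109 to 0.0932, and the smallest limma adjusted p became 0.0756. What ended the calls was not tested further. For the other settings that moved a count, the cause was not tested, beyond the larger number of replicates where arrays were entered singly and the fewer genes without whole numbers.

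With an estimated correlation 0 of the 13 lists passed in tetYFH1 and 0 of the 17 in the difference, on pair means and on arrays; without whole numbers reserve carbohydrates, oxidative stress and the proteasome lost their calls in tetYFH1, 11 passed in the difference, and the lists of lysine synthesis and of YFH1 had too few genes left for a value. Adr1 targets, general stress, glyoxylate and gluconeogenesis, quiescent cells and cytosolic ribosomal proteins passed in tetYFH1 in every other setting run on lists. Across genes, r between strains was 0.486 in the 25 genes (−0.0892 in all).

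Some signs reversed when an array or pair was left out, in no case for a gene that had passed, since those lay below 0 on every tetYFH1 array. The reserve carbohydrate median in tetYFH1 ranged from −0.969 (without pair A) to 0.145 (without pair B), the RPN2 log2 ratio in tetYFH1 from −0.876 to 0.0344 and the RPN4 log2 ratio in tetYFH1 from −0.832 to 0.00551 likewise. The HEM25 log2 ratio in tetYFH1 ranged from −0.461 (without B2) to 0.0851 (without B1), and the HEM25 log2 ratio, tetYFH1 minus W303, from −0.423 to 0.124 likewise. The MRPS12 log2 ratio in tetYFH1 ranged from −0.174 (without B1) to 1.61 (without B2), and the EXP1 log2 ratio in tetYFH1 from −0.184 (without B1) to 0.00112 (without B2). For sulfur amino acids without whole numbers the test of the difference turned down (median 0.0491). The cause was not tested.

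The direction of the W303 ratios rests on the labels. With them turned, 3 genes passed in the difference (GRE1, FDH1 and CHA1), r became 0.0892, and 9 lists passed in the difference in place of 17, 6 of them among the 17. Of these 6, Adr1 targets, general stress genes and the glyoxylate cycle passed in the same direction as before. Ergosterol synthesis, ribosome biogenesis and mitochondrial ribosomal proteins passed in the opposite direction. The direction of the set test on the difference, which follows the mean statistic and not the median, reversed for the ATP synthase (median 0.122), reserve carbohydrates (0.482), heat shock chaperones (0.411), lysine synthesis (0.126), sulfur amino acids (−0.0740), ergosterol synthesis (−0.308), ribosome biogenesis (−0.377) and mitochondrial ribosomal proteins (0.664). The median changed sign, but the test direction did not, for oxidative stress (0.187), the proteasome (0.0709) and quiescent and sporulating cells (0.164). Of the genes entered for the difference, 33 changed sign and 44 did not, and none of the 33 passed. The difference became negative for ERG1 (−1.11), NOP14 (−1.07), UTP18 (−0.988), UTP4 (−0.901), MET17 (−0.610), MRH1 (−0.604), CBF5 (−0.595), LYS9 (−0.553), LYS20 (−0.542), ERG11 (−0.475), RPL42A (−0.448), ERG3 (−0.420), MMP1 (−0.323), ERG5 (−0.276) and RPL8B (−0.258). It became positive for PRE2 (0.0775), HSP104 (0.132), EXP1 (0.149), RSM24 (0.296), SPG1 (0.313), RPT6 (0.315), ICL1 (0.427), TSA2 (0.464), MRPL31 (0.557), PGM2 (0.579), MRPL1 (0.582), SSA4 (0.742), MRPL38 (0.760), GDB1 (0.761), CIT2 (0.857), MDJ1 (1.01), HSP42 (1.09) and TPS3 (1.24). The log2 ratios in W303 change sign by construction: RGI1 (−2.37), AIM17 (−1.89), GAP1 (−1.88), CIT2 (−1.78), HSP42 (−1.70), PWP1 (1.54), MRH1 (1.57), STL1 (1.61), SIP18 (1.98) and GRE1 (3.22).

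Not run, as nothing would change, were ORFs measured on all arrays, medians of several probes and a floor on linear ratios. Signal over background is not given in the sources used here.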

Other observations

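The values here were chosen after they were seen, and no test was run on them beyond those already given.

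Within the iron regulon, single genes differed between the tetYFH1 pairs and none passed. The iron oxidase FET3 read 0.56 and 0.46 in pair A and 2.00 and 1.78 in pair B, and its partner, the permease FTR1, 0.15 and −0.10 against 1.44 and 1.80. Of the 4 siderophore transporters, ARN1 and SIT1 were below 0 in pair A and above it in pair B: ARN1 read −0.64 and −0.57 against 2.00 and 1.00, and SIT1 −0.58 and −0.79 against 2.00 and 1.00. ARN2 read −1.42 and −1.58 against 0.00 and −0.03, and ENB1 0.44 and 0.61 against −0.997 and 0.28. The log2 ratio of the regulator AFT1 was 0.28 in tetYFH1 and that of TIS11, which binds messenger RNAs of iron-using proteins, was 0.13.

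The genes of leucine, isoleucine and valine synthesis had a median log2 ratio of −0.46 in pair A and 0.47 in pair B. LEU1, an iron-sulfur enzyme, read −1.71 and −1.41 in pair A and −0.08 and 0.51 in pair B. OAC1 read −0.94 and −1.22 against 1.00 and 0.39, and ILV5 −0.80 and −0.79 against 2.00 and 1.00.

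The regulators of the genes that fell were themselves near 0 in tetYFH1 and did not pass: ADR1 had a mean log2 ratio of 0.16, CAT8 −0.29, MSN2 0.29 and MSN4 −0.21. The hexose transporters HXT2 (−1.62) and HXT5 (−1.71) and the external NADH dehydrogenase NDE2 (−1.87) had low means without passing. CIT2, a target of the retrograde pathway, read −0.11 and −0.35 in pair A, −1.76 and −1.49 in pair B, and 1.57 and 2.00 in W303.

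Across genes, which are not independent replicates, the arrays of a pair had an r of 0.596 (A1 with A2), 0.399 (B1 with B2) and 0.236 (W303). Between pair A and pair B arrays r lay between 0.197 and 0.324. Between pair B and W303 arrays it lay between −0.221 and −0.0565, if the W303 ratios run as labelled.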
